A study of Mus musculus with 4 samples.

How the data were processed

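RNA of 4 samples of mouse embryonic fibroblasts was hybridised to Affymetrix MOE430A arrays, 1 array per sample: 2 controls with an empty retroviral vector and 2 samples with the vector carrying mTert. Samples were grouped, and numbered 1 and 2 within each group, by their titles. The authors deposited 1 intensity per probe set and array on a linear scale, which per the file headers is a value with a present, marginal or absent call. They also deposited a detection p-value for each probe set, per the file headers. The software that summarised the probes and made the calls is not given in the sources used here. The mean signal after leaving out the lowest and highest 2% of probe sets was 498.593, 498.709, 498.636 and 498.779 on control 1, control 2, mTert 1 and mTert 2, so the arrays had been brought to 1 level before deposit. The authors' series table held the same intensities, with a largest difference of 0. The instrument records gave the chip type, the amount of labelled cRNA, the wash module and the order of scanning.

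The median signal was 210.15, 221.55, 224.1 and 218.6 on control 1, control 2, mTert 1 and mTert 2. The recorded amount of cRNA was 5 µg for control 1 and 15 µg for each other array. The ratio of the 3' to the 5' control probe set was 1.22, 1.14, 1.16 and 1.20 for actin and 0.773, 0.837, 0.823 and 0.820 for Gapdh, in the same order. The arrays were scanned 11, 0, 22 and 91 minutes after the first scan, each through its own wash module, so no wash module or scan held more than 1 array. Leaving out control 1 gives the comparison within the 15 µg arrays. It sets control 2 alone against both mTert arrays, so it also holds part of the difference between arrays numbered 1 and 2. The number of arrays limits the precision of all values.

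Each array's signal was scaled to a common trimmed mean over probe sets that are not controls and taken to log2. The 1 signal at 0 was set to the lowest present signal of its array. The 64 control probe sets were left out, as were probe sets called present on fewer than 2 of the 4 arrays, whatever their group, which left 12396. Gene symbols came from GEO's platform annotation: 20380 probe sets had 1 symbol, 691 several and 1555 were not listed, and no symbol needed updating. Of the tested probe sets, 11421 had 1 symbol, for 7387 genes. No gene was named from a probe set with several symbols.

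The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, prior degrees of freedom 4.13), without a replicate term, and p-values were adjusted by Benjamini and Hochberg over all probe sets tested at a threshold of 0.05. For Tert, absent in both controls, the fold is a lower bound: the mTert mean against, per control array, the higher of its own signal and the lowest present signal of that array, as means of log2 values. Macrophage genes absent on both arrays numbered 1 were given the same kind of bound. Gene lists were tested with camera at a preset correlation of 0.01, on 1 probe set per gene (the brightest on average), for the 31 of 33 lists with at least 5 measured members, and with camera at an estimated correlation and fry. List medians were set beside those of 10000 random lists of the same size matched on mean signal. The groups, the fit, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The TGF-beta and matrix lists were included because of the study's interest in that pathway, as publicly known.

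The genes named are Tert, 12 genes per direction and 4 members of each list. The 12 were to be those with the largest change among probe sets past the threshold whose groups do not overlap and that have 1 symbol that is not a clone name. The 4 list members are those with the smallest p, of which some were left out for lists that passed no test. As no probe set passed, the 12 places in each direction were filled by the smallest limma p. Other genes named for the immediate-early list and among the macrophage, interferon, contractile and cholesterol genes were chosen after their values were seen.

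The limma step was tested on simulated data of 12396 probe sets with the noise of this comparison, with 200 changed probe sets in each of 20 runs. It recovered 2.3% of changes of 0.5 on the log2 scale, 38.6% of changes of 1, 87.8% of changes of 2 and 96.7% of changes of 3, with 6.1 false calls per run. These shares rest on the 200 planted changes, since the adjusted threshold is stricter where fewer probe sets change. In the data Tert, with a log2 difference of 3.25, had a limma adjusted p of 0.188 and was not called. A list shifted by -0.4 was called in 20 of 20 runs by camera with the preset correlation, in 0 with an estimated one and in 5 by fry, and an unshifted list in 0 by each. The simulation held no difference between arrays numbered 1 and 2. Its noise was drawn independently for each probe set, so it does not measure false calls of the preset test among correlated genes. In the data the estimated correlation was 0.083 for the immediate-early list, 0.115 for chaperones and 0.194 for mitosis. It was 0.054 for TGF-beta targets and -0.0015 for growth factors.

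The alternatives were a replicate block, quantile normalization, the signals as deposited, centring on the median, a pseudocount of 32, no intensity trend, the series table, no filter on calls, presence on all 4 arrays, the mean over a gene's probe sets, an adjusted p of 0.10, a fold of at least 1.5, and leaving out each array in turn. Added after seeing the data were the TGF-beta target and growth factor lists without immediate-early genes and the other ways of splitting the 4 arrays into 2 pairs.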

Results

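Gene expression was measured in mouse embryonic fibroblasts (MEFs), cells grown from mouse embryos, on 4 Affymetrix MOE430A arrays. The cells had received a retrovirus built on pBabePuro, a vector that carries puromycin resistance. In the 2 control samples the vector was empty, and in the 2 mTert samples it carried Tert, the gene of the catalytic subunit of mouse telomerase. Of the 22690 probe sets on each array, 12298 and 11977 were called present in control 1 and control 2, and 11681 and 12244 in mTert 1 and mTert 2, or between 51.6% and 54.4% of those that are not controls. Signals are given as mean ± SD of 2 arrays in scaled arbitrary units, and fold changes as mTert over control on the log2 scale with the standard error (SE) of limma. Nothing in the labels says whether arrays of one group came from separate cultures, so each p-value measures only the spread between these samples, which may be in part technical.

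The transgene's gene was examined in every sample first. Tert, read by a single probe set, was called absent in both controls, with signals of 128 and 84.7. It was called present in both mTert samples, with signals of 1164.5 and 845. The mean was 106 ± 30.6 in control and 1005 ± 226 in mTert, a log2 difference of 3.25 (SE 0.26). Because the control signal was not above background, this stands for at least 9.53-fold higher Tert signal with the transgene, as a ratio of geometric means. Tert had the smallest p of all probe sets, and its limma adjusted p was 0.188 over the 12396 probe sets tested. It was 0.00027 when adjusted over the list alone, the list being 20 genes of telomerase and telomere upkeep. The other members of that list with the smallest p were Pinx1, an inhibitor of telomerase, at -0.29 (SE 0.17), Nbn at -0.21 (SE 0.16) and Rad50 at 0.14 (SE 0.14). The list as a whole had a median of -0.012 but a mean of 0.17 and a test direction of higher (camera adjusted p = 0.644). It includes Tert itself, whose 3.25 raises the mean, while 12 of the 20 members were lower and 8 higher in sign.

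The comparison of mTert with control asked which other transcripts differ in fibroblasts that express the telomerase subunit. Of the 12 genes with the smallest p on the lower side, 8 were in the list of immediate-early genes, which cells induce within minutes of stimulation. Klf10, a repressor induced by TGF-beta, had a signal of 1767 ± 93.3 in control and 883 ± 37.4 in mTert. It was 2.00-fold lower, with an SE of 0.11 on the log2 scale. Egr2 had 1288 ± 52.0 in control and 620 ± 113 in mTert, and Junb, an AP-1 subunit, 5393 ± 444 and 2983 ± 399. On the higher side, among probe sets with 1 gene symbol, the smallest p after Tert belonged to Chd6, a chromatin remodeller, with 209 ± 42.7 in control and 439 ± 36.4 in mTert, and to Txnip, the thioredoxin-interacting protein, with 985 ± 154 and 1721 ± 235. In the fit without a replicate term none of these differences passed the test over all genes. At an adjusted p of 0.05 limma then called 0 probe sets higher and 0 lower, the smallest adjusted p being that of Tert. With a replicate block limma called 18 probe sets, 3 higher and 15 lower. Klf10, Egr2, Junb, Chd6 and Txnip were among them, with limma adjusted p between 0.00026 and 0.041.

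The remaining lower genes, given by the size of the difference, were Nr4a1 at -0.81 (SE 0.11), Gadd45b at -0.80 (SE 0.14), Btg2 at -0.78 (SE 0.11) and Klf9 at -0.67 (SE 0.10). Smaller differences were those of Fosb at -0.63 (SE 0.11), Zfp36 at -0.62 (SE 0.12), Bhlhe40 at -0.59 (SE 0.10), Klf4 at -0.49 (SE 0.09) and Ier2 at -0.46 (SE 0.09). Nr4a1 is an orphan nuclear receptor, Btg2 an antiproliferative gene, Gadd45b a stress gene and Zfp36 a protein that destabilises messenger RNAs with AU-rich elements. In the fit without a replicate term the limma adjusted p of the 12 lower genes ran from 0.695 for Klf10 to 1.00. All other tested probe sets of Btg2 (1), Egr2 (1), Klf9 (4), Gadd45b (2) and Klf4 (1) lay on the same side. The other higher genes, again by size, were Kif18a, a mitotic kinesin, at 0.87 (SE 0.23), Farsa at 0.69 (SE 0.17), Idnk at 0.67 (SE 0.17), Trip4 at 0.59 (SE 0.15) and Ercc6l2 at 0.58 (SE 0.14). Ndufa7 stood at 0.53 (SE 0.13), Sorcs2 at 0.50 (SE 0.12), Lmna, which encodes A-type lamins, at 0.38 (SE 0.10) and Cd99 at 0.35 (SE 0.08). The limma adjusted p of these genes was 1.00 in the same fit. These had less backing from other probe sets: the second Lmna probe set lay on the opposite side, at -0.20, as did 1 of 2 others for Cd99, 1 of 2 for Ercc6l2 and 1 of 4 for Ndufa7. The other probe sets of Txnip (1) and Trip4 (2) lay on the same side.

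Across all probe sets, 261 had an unadjusted limma p under 0.05 in the fit without a replicate term, 105 higher and 156 lower in mTert. Chance alone gives 619.8, so this fit was conservative and its lack of calls is weak evidence that genes do not differ. With a replicate block 488 probe sets had such a p, which is also fewer than chance alone gives. The 2 mTert signals lay entirely above the 2 control signals for 1662 probe sets and entirely below for 1502, together 25.5%, where chance gives 33.3%. Of these, 45 of the higher and 71 of the lower ones differed at least 1.5-fold. Between any 2 arrays Pearson's r across probe sets, which are not independent replicates, lay between 0.971 and 0.984. It was 0.984 for control 1 with mTert 1 and for control 2 with mTert 2, 0.973 for the other 2 pairs of a control and an mTert array, and 0.971 within each group.

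Immediate-early genes, the genes that serum and growth factors induce within minutes without new protein synthesis, were lower as a group in mTert cells. Among the list tests, only camera with the preset correlation called this shift. Of 29 measured members 26 had a lower mean in mTert and 3 a higher one, with a median log2 difference of -0.45 (quartiles -0.59 and -0.22). In 23 members both mTert signals lay below both control signals and in 2 above. Chance gives 33.3% of members in both directions together if the arrays are exchangeable, and all tested probe sets gave 25.5%. The members with the smallest p were Nr4a1, Junb, Btg2 and Egr2, and the list also held Ier3 at -0.59, Dusp6 at -0.60, Atf3 at -0.52, Myc at -0.52 and Jun at -0.44. Egr1 and Fos, whose signals in control were 13990 ± 588 and 11138 ± 318, stood at -0.26 and -0.18. Fosl2 (0.33) and Plaur (0.20) were the members whose mTert signals both lay above the controls, and Srf (0.02), Vcl (-0.02) and Ccn2 (-0.08) differed little. Of the 29 members, 19 fell when adjusted over the list alone and 0 passed over all genes tested, in the fit without a replicate term. With a replicate block 21 fell when adjusted over the list alone. Of the genes that limma called with the block over all probe sets, 8 were members.

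The list fell by limma's camera with a preset correlation of 0.01 between genes (adjusted p = 2.2e-33 over 31 lists). The call did not hold with an estimated correlation (adjusted p = 0.511, unadjusted 0.016) or by limma's rotation test fry (adjusted p = 0.376, unadjusted 0.024). In simulated data a list shifted by -0.4 was called in 0 of 20 runs with an estimated correlation and in 5 by fry. These failures therefore do not argue against a shift. Relative to the mean of the 4 arrays, the list mean was 0.21 in control 1, 0.18 in control 2, -0.14 in mTert 1 and -0.25 in mTert 2 on the log2 scale. In each of the 4 pairings of a control with an mTert array between 23 and 27 of the 29 members were lower in mTert. The count of 19 members was 8 without mTert 2, 12 without control 2 and 12 without mTert 1. Taken as 1 value per array, the list cannot pass an exact permutation test, since 2 against 2 arrays allow no two-sided p under 0.333.

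**Figure D1:**
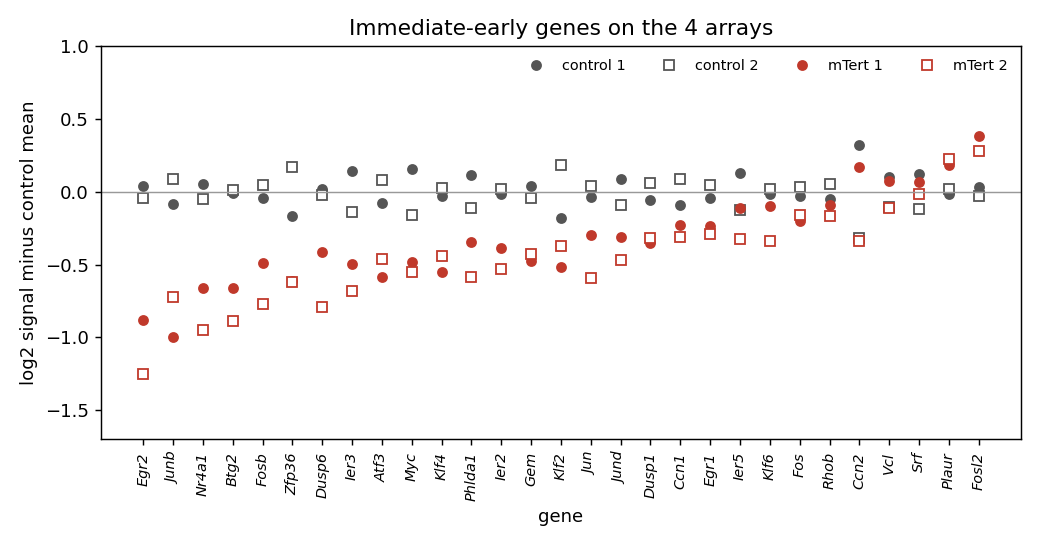
Log2 signal of the 29 measured immediate-early genes on each of the 4 arrays, minus the mean log2 signal of that gene in the 2 controls (grey, control; red, mTert; filled circles, arrays numbered 1; open squares, arrays numbered 2). Both mTert arrays lie below both controls for 23 genes and above both for Fosl2 and Plaur.

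Targets of TGF-beta signalling had a median log2 difference of -0.036 over 40 members and a mean of -0.099. Klf10 and Junb fell when adjusted over the list alone. Over all genes 0 members passed without a replicate term, and Klf10 and Junb passed with a replicate block. Next by p came Id3 at -0.37 (SE 0.10) and Id1 at -0.45 (SE 0.13), inhibitors of helix-loop-helix factors that respond to TGF-beta and BMP signals. The list passed camera with the preset correlation (adjusted p = 0.016) but not with an estimated correlation (adjusted p = 0.716) or by fry (adjusted p = 0.908). The latter tests called a simulated list shifted by -0.4 in few runs or none. Without the 3 members that the target list shares with the immediate-early list, a choice made after seeing the data, its camera adjusted p was 0.130. Its median was then -0.030. The list also missed the threshold after quantile normalization. With 1 array left out its median was 0.00023 without control 1 and 0.051 without mTert 2. It was -0.113 without control 2 and -0.061 without mTert 1. Such fits also hold part of the difference between arrays numbered 1 and 2.

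The receptors, ligands and intracellular components of the TGF-beta pathway themselves had a median of -0.029 over 25 members and did not pass camera with all 4 arrays (adjusted p = 0.275). Their members with the smallest p were Tgif1, a corepressor of Smads, at -0.32 (SE 0.12), Acvr1 at -0.30 (SE 0.14), Skil at -0.20 (SE 0.10) and Ltbp2 at 0.14 (SE 0.10). The 41 extracellular matrix genes centred on -0.003 (adjusted p = 0.396), with Mfap2 at -0.38 (SE 0.13), Vcan at -0.32 (SE 0.12), Eln at -0.64 (SE 0.25) and Col5a1 at 0.17 (SE 0.07). Matrix proteases and their inhibitors stood at 0.050 over 19 members (adjusted p = 0.275), led by Timp1 at 0.41 (SE 0.12). The contractile genes of myofibroblasts centred on 0.00025 over 18 members, with a test direction of lower (adjusted p = 0.817). With 1 array left out the matrix median was -0.078 without control 2 and -0.039 without mTert 1. It was 0.040 without control 1 and 0.0018 without mTert 2. The contractile median was 0.17 without control 1 and 0.10 without mTert 2, but -0.15 without control 2 and -0.11 without mTert 1. Each such fit leaves the numbers 1 and 2 unequal between the groups, so it holds part of the difference between numbers. Between arrays numbered 2 and 1 the medians were -0.085 for matrix and -0.24 for contractile genes. These sign changes therefore cannot be read as an effect of mTert.

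Growth factors and their receptors had a median of -0.082 over 37 members, 27 of them lower in sign. Hbegf, an EGF receptor ligand, had the smallest p, with 4092 ± 147 in control and 2309 ± 686 in mTert, a log2 difference of -0.86 (SE 0.20). Its other probe set stood at -1.09, and both probe sets passed over all genes with a replicate block. Pdgfa at -0.35 (SE 0.17), Erbb3 at -0.44 (SE 0.24) and Vegfa at -0.28 (SE 0.15) followed, and 0 members passed when adjusted over the list alone. Heat shock proteins and chaperones had a median of -0.057 over 18 members, 14 of them lower in sign. The smallest p belonged to Dnajb1 at -0.47 (SE 0.10), the endoplasmic reticulum chaperone Hspa5 at -0.26 (SE 0.07), Bag3 at -0.34 (SE 0.14) and Hmox1 at -0.23 (SE 0.11). Genes of mitosis and the G2/M phase lay on the other side, with a median of 0.12 over 36 members, 30 of them higher in sign. Kif20a stood at 0.51 (SE 0.23), Ect2 at 0.33 (SE 0.21) and Tacc3 at 0.40 (SE 0.29), whereas Smc4 stood at -0.28 (SE 0.19). Adjusted over the list alone, 0 members of the chaperone and mitosis lists passed.

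These 3 lists passed camera with the preset correlation (adjusted p = 0.0092 for growth factors, 0.0092 for chaperones and 0.017 for mitosis). They also passed it with a replicate block (camera adjusted p = 0.00028, 0.0068 and 0.022). None held with an estimated correlation (adjusted p = 0.716, 0.716 and 0.748) or by fry (adjusted p = 0.880, 0.893 and 0.893). Both tests seldom or never called a simulated list with a larger shift of -0.4, so these failures leave the lists undecided. The calls also depended on single arrays. Growth factors stood at -0.038 without control 1 or mTert 2, and mitosis at 0.012 without control 2. Chaperones stood at 0.011 without control 1 and -0.031 without mTert 2. Such fits also hold part of the difference between arrays numbered 1 and 2. The growth factor call ended with no filter on calls (camera adjusted p = 0.092). The mitosis call ended on probe sets present on all arrays (camera adjusted p = 0.0503).

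Genes tied to senescence and growth arrest did not pass camera with all 4 arrays and no replicate term. The cyclin-dependent kinase inhibitors and other senescence genes had a median of -0.071 over 20 members (adjusted p = 0.130), with Id1 at -0.45, Cdkn1b at -0.24 (SE 0.14), Ets1 at -0.30 (SE 0.23) and Bmi1 at -0.16 (SE 0.14). Secreted and inflammatory genes of senescent cells had a median of -0.092 over 21 members (adjusted p = 0.166), led by Ptgs2 at -0.44 (SE 0.22) and Ereg at -0.43 (SE 0.22). Targets of p53 had a median of 0.052 but a mean of -0.017 over 22 members and a test direction of lower (adjusted p = 0.794). Btg2 and Gadd45b fell when adjusted over the list alone, and Bbc3 and Ddit4 stood at 0.25 (SE 0.13) and 0.37 (SE 0.21). DNA repair genes centred on 0.079 over 31 members (adjusted p = 0.251), with Polb at 0.37 (SE 0.16) and Ercc1 at 0.32 (SE 0.15). DNA replication and S phase genes centred on 0.012 over 35 members (adjusted p = 0.358), with Rpa2 at 0.83 (SE 0.25) and Mcm3 at 0.34 (SE 0.13). The apoptosis list centred on 0.0090 over 21 members, with a test direction of lower (adjusted p = 0.794). Mcl1, an antiapoptotic BCL2 relative, had the smallest p in it at -0.40 (SE 0.09). With a replicate block camera called the list of kinase inhibitors and other senescence genes (adjusted p = 0.035) and the secreted genes (adjusted p = 0.020) lower. Of the 20 members of the former, 9 were higher and 11 lower in sign. The kinase inhibitors themselves lay on both sides, such as Cdkn2b at 0.23 and Cdkn1c at -0.29. With 1 array left out the list of kinase inhibitors and other senescence genes stood at -0.126 without control 2 and -0.099 without mTert 1. The secreted genes stood at -0.213 without mTert 2 and p53 targets at -0.102 without control 2. Such a fit also holds part of the difference between arrays numbered 2 and 1. That difference was -0.126 for kinase inhibitors with other senescence genes, 0.167 for secreted genes and -0.239 for p53 targets.

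None of the metabolic and biosynthetic lists passed with all 4 arrays, except oxidative phosphorylation after quantile normalization (0.052, adjusted p = 0.031). Oxidative phosphorylation had a median of 0.042 over 49 members (adjusted p = 0.206), glycolysis and hypoxia genes 0.0092 over 27 (adjusted p = 0.644) and cholesterol synthesis -0.043 over 21 (adjusted p = 0.322). The median was -0.0045 for ribosomal proteins over 28 members (adjusted p = 0.794) and -0.026 for targets of MYC with ribosome biogenesis genes over 35 (adjusted p = 0.275). The unfolded protein response centred on -0.012 over 22 members (adjusted p = 0.350), with Atf3 at -0.52 and Hspa5 at -0.26 as the members of smallest p. Oxidative stress genes under NRF2 centred on 0.023 over 24 members (adjusted p = 0.794), Wnt signalling on -0.032 over 27 (adjusted p = 0.275) and interferon-responsive genes on 0.097 over 26 (adjusted p = 0.530). The interferon median was -0.27 without control 1 and -0.32 without mTert 2, but 0.51 without control 2 and 0.46 without mTert 1. Cholesterol synthesis stood at -0.14 without control 2 and -0.19 without mTert 1, but at 0.18 without mTert 2. The MYC list stood at -0.077 without control 2. Such fits also hold part of the difference between arrays numbered 2 and 1. That difference was 0.67 for interferon, -0.30 for cholesterol and -0.030 for MYC genes.

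Markers of cell types that a fibroblast culture can hold did not pass camera between the groups with all 4 arrays. Fibroblast markers had a median of -0.044 over 18 members (adjusted p = 0.098), with Vim at -0.17 (SE 0.06). Macrophage and leukocyte markers had a median of 0.12 over 19 members (adjusted p = 0.794), and cartilage and bone markers 0.0030 over 9 (adjusted p = 0.794). The median was -0.053 for neural and glial markers over 8 members (adjusted p = 0.296) and 0.15 for adipocyte markers over 5 (adjusted p = 0.794). Epithelial markers had a median of -0.011 but a mean of 0.020 over 6 members (adjusted p = 0.794). Macrophage markers did differ several-fold within each group: C1qa had a signal of 39.8 in control 1 and 39.8 in mTert 1, and of 1189 in control 2 and 1395 in mTert 2. The macrophage median was -0.89 without control 1 or mTert 2, but 1.35 without control 2 and 1.24 without mTert 1. The fibroblast median was -0.063 without control 2 and -0.047 without mTert 1. Such fits hold part of the difference between arrays numbered 2 and 1. That difference was 2.18 for macrophage and -0.050 for fibroblast markers. The lists of endothelial and skeletal muscle markers had fewer than 5 measured members and were not tested.

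**Figure D2:**
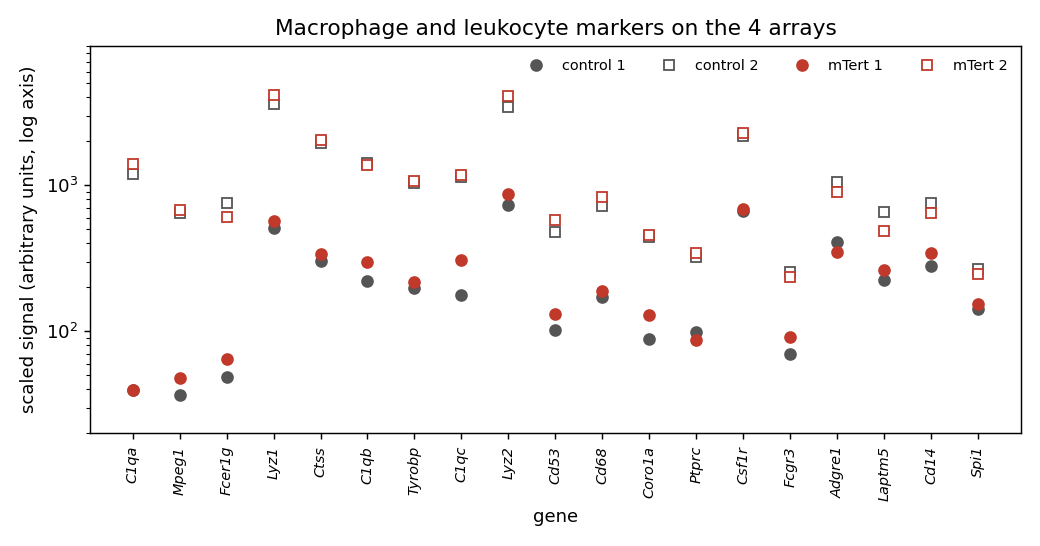
Scaled signal, on a log axis, of 19 macrophage and leukocyte markers on each of the 4 arrays (grey, control; red, mTert; filled circles, arrays numbered 1; open squares, arrays numbered 2). All 19 markers lie higher on both arrays numbered 2 than on both arrays numbered 1, while the median log2 difference between mTert and control is 0.12.

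**Figure D3:**
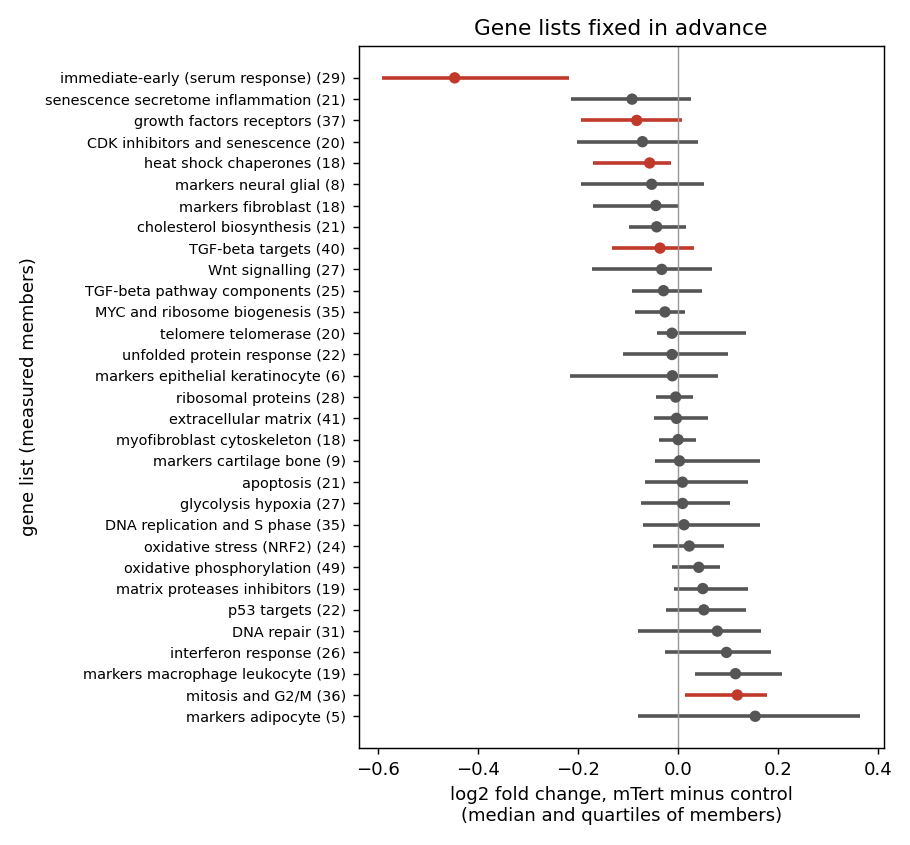
Median (point) and quartiles (line) of the log2 fold change, mTert minus control, over the measured members of each of the 31 lists tested, with the number of members in parentheses. Lists in red passed limma's camera with the preset correlation at an adjusted p of 0.05. None of them held with an estimated correlation, which called a simulated list shifted by -0.4 in 0 of 20 runs. The immediate-early list has the lowest median, -0.45.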

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

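The tests in this part were chosen after the results were seen. On mTert 1, and on no other array, the 5' and 3' control probe sets for 18S ribosomal RNA were called present: the 5' probe set read 655.1 on mTert 1 against at most 6.1 on the controls and 3 on mTert 2, and the 3' probe set read 689.8 against at most 151.9 on the controls and 92.8 on mTert 2.

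The immediate-early genes had a median of -0.45 on the log2 scale in mTert against control. A bias of bright probe sets or of the scaling is argued against: the medians of 10000 random lists matched on mean signal had a central 95% range from -0.044 to 0.028. Lying outside such a range is not a strict criterion. The macrophage markers, which did not pass camera between the groups with all 4 arrays, had a median of 0.115 against a range from -0.067 to 0.106. A difference in leukocyte content is argued against as well, because between arrays numbered 2 and 1, where leukocyte markers differ several-fold, the list's median was -0.097. Serum, medium change or handling at harvest that differed between the groups cannot be told apart from an effect of mTert: the list mean differed by -0.39 between the groups and by at most 0.12 within one, as either would give, and the labels do not describe the harvest. An effect of mTert on these genes thus stays a hypothesis, and so does a difference between the infected cell populations that does not stem from the transgene.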

How the results depend on the processing

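The other splits of the arrays and the lists without immediate-early genes were chosen after seeing the data. The count of probe sets was 0 under every setting except a replicate block, which gave 18 (3 higher, 15 lower, for 16 genes, 8 of them immediate-early) and 488 at an unadjusted p under 0.05 where the fit without it had 261. The titles share only the numbers 1 and 2, and same-numbered arrays' deviations from their group means correlated at 0.373. Split as arrays numbered 1 against arrays numbered 2, the 4 arrays gave 192 probe sets where the labelled groups gave 0, which points to a structure of the samples. The crossed split, control 1 and mTert 2 against control 2 and mTert 1, gave 0. At an unadjusted p under 0.05 the numbers gave 1305, the crossed split 550 and the labelled groups only 261. Tert stayed at 3.25 with the replicate block, its adjusted p then 9.6e-08, and over the alternatives without the block that p ran from 0.109 to 1.00. Of 31 lists, 5 passed, but 0 with an estimated correlation and 0 by fry, and from 5 to 13 with 1 array left out (13 without control 2, 12 without mTert 1); there the lone array is assumed to vary like the others. The immediate-early median ran from -0.35 to -0.45 and passed camera with the preset correlation in every setting; its members past the threshold over the list alone numbered from 8 (without mTert 2) to 16 (without control 1) with 1 array left out and from 13 (no intensity trend) to 21 (replicate block) otherwise. Estimated correlation and fry ended the 5 list calls at unchanged medians (-0.45 for immediate-early genes, adjusted p 0.511 and 0.376; -0.082 for growth factors, 0.716 and 0.880; -0.057 for chaperones, 0.716 and 0.893; -0.036 for TGF-beta targets, 0.716 and 0.908; 0.12 for mitosis, 0.748 and 0.893). In simulated data these tests called a list shifted by -0.4 in 0 and 5 of 20 runs, so the lost calls do not argue against the lists. Calls also ended for TGF-beta targets after quantile normalization (-0.024) and without immediate-early members (-0.030), for growth factors with no filter on calls (-0.064) and for mitosis on probe sets present on all arrays (0.097). With the replicate block the 5 list calls held. Among the other lists, camera newly called 1 after quantile normalization, 2 with the replicate block and others with 1 array left out. The 2 were kinase inhibitors with other senescence genes (camera adjusted p 0.035) and secreted senescence genes (0.020). With 1 array left out the medians ran from -0.11 to 0.051 for TGF-beta targets and -0.166 to -0.038 for growth factors. They ran from -0.165 to 0.011 for chaperones and 0.012 to 0.16 for mitosis. Such fits leave the numbers 1 and 2 unequal between the groups, so they hold part of the difference between numbers. That difference was -0.093, -0.025, -0.064 and -0.037 in the same order. TGF-beta targets, growth factors and chaperones moved in the direction it gives. Mitosis moved against that direction without mTert 1 (0.148). How much of the movement the difference between numbers explains was not tested. Leaving immediate-early genes out of the growth factor list removed 0 genes, and the series table moved nothing. Of the 23 genes named by rank besides Tert, 0 changed sign in any setting and 13 passed the threshold, all with the replicate block. Signal over background limits Tert: the controls give only a bound on its fold.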

Other observations

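The tests and comparisons in this part were chosen after the results were seen. Macrophage and leukocyte genes were far higher on the arrays numbered 2, in both groups. Their 19 measured markers had a median log2 difference of 2.18 between arrays numbered 2 and 1, or 2.22 between the controls and 2.12 between the mTert samples, and 18 of them passed limma's test over all probe sets. C1qa, a complement component made by macrophages, was at least 32.3-fold higher, Mpeg1 at least 15.8-fold and the Fc receptor subunit Fcer1g at least 12.2-fold. These 3 were among 9 of the 19 markers not called present on either array numbered 1. The abundant lysozyme gene Lyz1 and cathepsin gene Ctss, present on all arrays, were 7.13-fold and 6.25-fold higher. Interferon-responsive genes had a median of 0.67, with 23 of 26 higher on both arrays numbered 2. For exchangeable arrays chance gives 33.3% in both directions together. Of the interferon-responsive genes, 10 passed the threshold, such as Oasl2 (3.25-fold), Usp18 (3.11-fold) and Ifit1 (3.02-fold).

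Contractile genes lay the other way. The 18 myofibroblast cytoskeleton genes had a median of -0.24, with 15 lower on both arrays numbered 2, and Actg2 (-0.75), Tagln (-0.55) and Csrp1 (-0.47) fell past the threshold. Cholesterol synthesis genes had a median of -0.30, with 14 of 21 lower on both and Cyp51 (-0.69) and Fdps (-0.59) past it. Camera with the preset correlation called 10 of the 31 lists between the numbers, these 4 with the smallest p (adjusted p = 1.8e-50 for macrophage, 6.2e-22 for interferon, 9.1e-13 for contractile and 6.4e-09 for cholesterol genes). The other 6 were extracellular matrix genes (1.9e-05), p53 targets (4.5e-05), TGF-beta targets (0.00032), secreted senescence genes (0.017), chaperones (0.019) and kinase inhibitors with other senescence genes (0.030). With an estimated correlation 0 of the 31 lists passed, the 4 each having an adjusted p of 0.240.

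A candidate explanation is that the cultures numbered 2 held more leukocytes, which embryo preparations can carry along. The markers fixed before the data were examined were higher on both arrays numbered 2 for 19 of 19 genes, the abundant lysozyme and cathepsin genes included. Fibroblast markers had a median of -0.050. The 19 markers are the genes in which the difference was seen, so they describe it and do not test the explanation. Scaling or a bias that depends on signal level is argued against: the markers' median of 2.18 lay outside the central 95% of medians of 10000 random lists matched on mean signal, -0.091 to 0.125. Embryo, preparation or culture age could each go with the numbers and stay open, as the labels do not say what a number stands for.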
